A study of Homo sapiens with 50 samples.

How the data were processed

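RNA of differentiated HepaRG cells was sequenced in 50 libraries, 5 in each of 10 groups. Per the labels' protocols, total RNA libraries were made with a stranded kit that removes ribosomal RNA, in random order, and sequenced as 75 bp paired reads in 3 pools of 17, 17 and 16 libraries; which library lay in which pool is not given in the sources used here. The submitters' processing notes name HISAT, HISAT2, StringTie and the build GRCh38, with no versions and no role for each.

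The authors deposited 1 table of FPKM values, which scale fragments by transcript length and library size, for 239290 transcripts, 199173 of them with an Ensembl name and 40117 assembled, with coordinates. FPKM divides by the fragments of a library, so RNA that takes many fragments lowers every other value, and it removes differences in depth but not the larger error of a shallow library. All value columns matched 1 sample by title. The table held 24 values slightly below 0, which were set to 0, and 1 line broken over several lines was rejoined. Depth is not in the table. It was estimated from the FPKM step that 1 fragment makes in 10250 single-exon transcripts of 300 to 1500 bp, and gives 7180000 to 34240000 fragments in 49 libraries and 3780000 in the last.

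Transcript FPKM were summed per gene, and 18349 unnamed transcripts went to the only named gene of their locus, which gave 74174 genes and loci. Genes with at least 1 FPKM in at least 5 of the 50 libraries were tested, 19676 in all. Values were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with 1 mean per group over all 50 libraries, moderated variance with trend and robust settings), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 9 groups exposed to a compound were compared with control, and the compounds with each other at each concentration, 9 direct comparisons. The tests, alternatives, gene lists and naming rule were fixed before the data were examined, except those stated below to be chosen after a result was seen.

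Named genes were, at 1 mM against control, the 10 that rose and the 10 that fell most among genes with an official symbol, a mean of 5 FPKM or more in the higher group and no overlap between the 5 treated and 5 control libraries, 5 and 5 at the lower concentrations, and 3 and 3 in direct comparisons. In a gene list up to 4 members past the threshold were named, and any member of the lists of tyrosine degradation, PPARalpha targets, CAR and PXR targets, and ALB. The 25 lists held textbook groups of liver metabolism, xenobiotic and stress responses and markers of cell types, and were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Not every gene that this rule picks is printed. For genes listed at 0 in some libraries the values of libraries are given.

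Unchanged groups against the same controls were simulated 50 times to set the covariance that shared controls give, and the controls were split 20 times. The fit was tested on simulated data for isoxaflutole at 1 mM against control with 19676 genes: of 50 genes changed by each factor it recovered 4 at 1.5-fold, 24 at 2-fold, 44 at 3-fold and 49 at 4-fold, and 3 of its 124 calls were unchanged genes. The simulated noise was independent between genes and had the same spread in every library, so correlated genes and an aberrant library were not simulated. The changed genes were drawn only from those at higher levels in control, so the recovery does not cover genes at low levels. No library column equalled another, and correlations of log2 values between libraries of a group ran from 0.776 to 0.964.

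Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, a fit of the 2 groups alone, the 5 runs of consecutive sample numbers in the titles as a block, each transcript tested by itself, and each library left out in turn. A fit of 49 libraries, without replicate 5 of quizalofop-p-ethyl at 10 uM, was added after seeing the data. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.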

Results

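Transcript levels were measured in differentiated HepaRG cells, a human hepatic cell line whose cultures hold hepatocyte-like and biliary-like cells. Cells were kept from day 8 to day 14 of culture with mesotrione, isoxaflutole or quizalofop-p-ethyl, each at 0.1 uM, 10 uM or 1 mM, next to 1 control group. Mesotrione, a triketone, and isoxaflutole, an isoxazole, are herbicides that block a plant enzyme of tyrosine degradation. Quizalofop-p-ethyl is a herbicide ester of the aryloxyphenoxypropionate class, which blocks fatty acid synthesis in grasses. The 10 groups held 5 libraries each, 50 in all. In 49 libraries the summed FPKM ran from 541900 to 801700, 14585 to 17951 genes reached 1 FPKM, and the estimated depth ran from 7180000 to 34240000 fragments. Replicate 5 of quizalofop-p-ethyl at 10 uM stood apart, with a summed FPKM of 234900, 6583 genes at 1 FPKM or more and an estimated 3780000 fragments. Loci of ribosomal RNA held 52.7% of its summed FPKM, against 1.10% to 3.79% in the other 49. It stayed in the fit, which shares 1 estimate of the spread over all 50 libraries, and counts are also given with 49 libraries, an alternative chosen after seeing the data. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Group values are mean ± SD of 5 libraries in FPKM. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0.

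**Figure D1:**
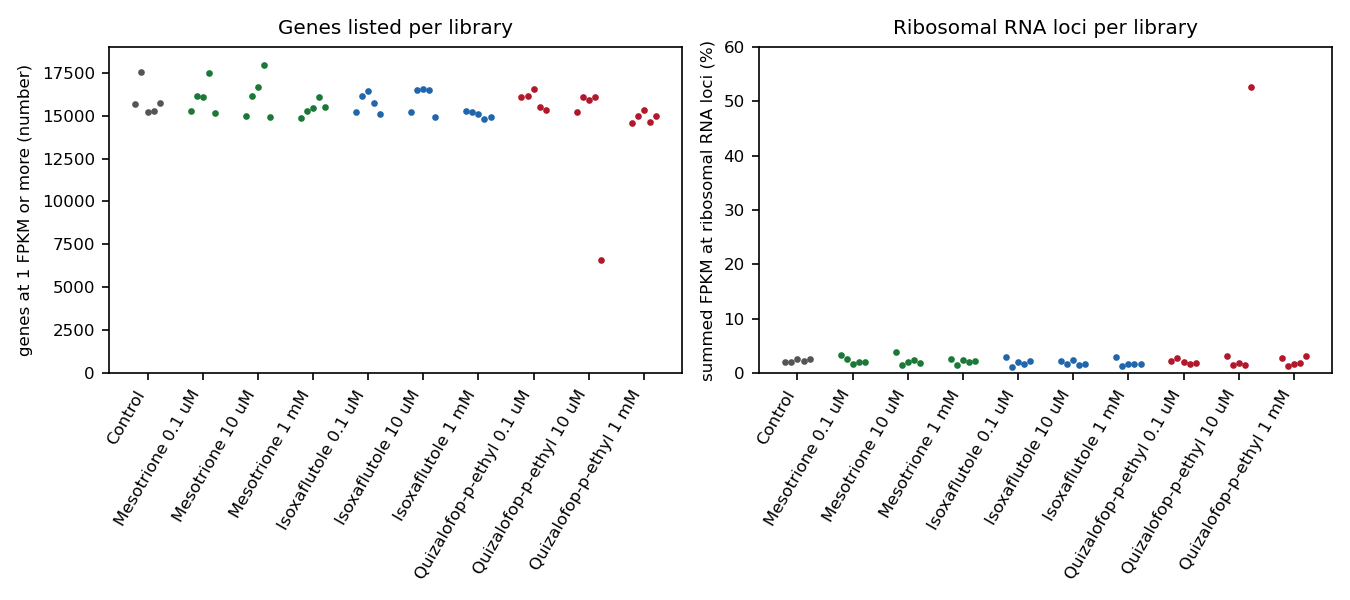
Genes at 1 FPKM or more (left) and percent of summed FPKM at ribosomal RNA loci (right), 1 point per library, by group. Replicate 5 of quizalofop-p-ethyl at 10 uM sits at 6583 genes and 52.7%, and the other 49 libraries lie between 14585 and 17951 genes and between 1.10% and 3.79%.

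Mesotrione at 1 mM raised CYP3A4, CYP1A1 and CYP1B1 and lowered COL3A1 and AHSG, among other genes. CYP3A4, a main drug-metabolising enzyme of the liver, rose from 2.76 ± 0.216 in control to 10.8 ± 5.08 (log2 fold change 1.56, SE 0.35, adjusted p = 0.0282; chromosome 7, 99756960 to 99784265, GRCh38). It shares sequence with CYP3A5 and CYP3A7, so its level is uncertain. Its call is not firm, since leaving out any single control library, or mesotrione replicate 2, 3 or 4, ended it. The dioxin-inducible enzymes CYP1A1 and CYP1B1 rose by 1.33 and 0.63 on the log2 scale, and ASNS, which makes asparagine, rose from 9.61 ± 0.791 to 17.7 ± 3.15. COL3A1, a chain of fibrillar collagen, fell from 17.7 ± 2.95 to 2.62 ± 0.905 (log2 fold change -2.40, SE 0.36, adjusted p = 0.000143; chromosome 2, 188974320 to 189012746). AHSG, which encodes the plasma protein fetuin-A, fell from 67.4 ± 10.4 to 18.3 ± 6.87 (log2 fold change -1.90, SE 0.36, adjusted p = 0.00492; chromosome 3, 186612923 to 186621318). SFRP2, CYP4F22, EPYC, VSIG1, IGFL1, KRT14, PGLYRP2 and IGFBP6 fell too, with log2 fold changes from -1.61 for SFRP2 to -0.84 for IGFBP6. ALB, the gene of albumin, did not pass, at 7892 ± 2071 against 9562 ± 637 (log2 fold change -0.32, adjusted p = 1).

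In all, 40 of 19676 genes passed limma's test against control with mesotrione at 1 mM, 6 higher and 34 lower. Of the 9 tested targets of the aryl hydrocarbon receptor (AHR), CYP1A1 and CYP1B1 rose and none fell, 2 also adjusted over the list alone. The AHR list ranked above other genes in limma's camera test (adjusted p = 1.81e-07), also with an estimated correlation between genes (adjusted p = 0.0149). Of 12 stellate and mesenchymal markers COL3A1 and DCN fell, 3 adjusted over the list alone (adjusted p = 9.17e-09, and adjusted p = 0.44 with an estimated correlation). Of 22 hepatocyte markers AHSG fell, 3 adjusted over the list alone (adjusted p = 1.15e-05, and adjusted p = 0.686 with an estimated correlation). Of 24 genes of the unfolded protein and integrated stress response ASNS rose, 5 adjusted over the list alone (adjusted p = 2.14e-05, and adjusted p = 0.573 with an estimated correlation). No member passed among 22 NRF2 targets, 2 being higher adjusted over the list alone (list upward, adjusted p = 2.54e-06, and adjusted p = 0.511 with an estimated correlation). None passed among 13 urea cycle and amino acid degradation genes, 2 being lower adjusted over the list alone (list downward, adjusted p = 8.17e-06, and adjusted p = 0.507 with an estimated correlation). Acute phase genes, biliary markers and leukocyte markers ranked lower with no member past the threshold, 1 in each being lower adjusted over the list alone. Their adjusted p were 0.00237, 0.00107 and 0.0159, and the adjusted p with an estimated correlation were 0.799, 0.507 and 0.507. Cell cycle genes ranked higher with no member past the threshold by either adjustment, over all genes or adjusted over the list alone (adjusted p = 0.0301, and adjusted p = 0.951 with an estimated correlation). With 49 libraries members passed in these lists too, 6 NRF2 targets higher, SRXN1 and SLC7A11 among them (adjusted p = 2.77e-05 and 0.001). Lower were 3 urea cycle genes, 2 biliary markers, 1 leukocyte marker and the acute phase gene CRP (2.62 ± 0.642 against 34.6 ± 38.1, log2 fold change -2.86, adjusted p = 0.00651), with none in the cell cycle list. The 5 tyrosine degradation genes did not pass, HPD, the human counterpart of the plant target, lying at 19.6 ± 2.10 against 24.6 ± 2.64 (log2 fold change -0.31, adjusted p = 1). Without the library high in ribosomal RNA 363 genes passed, 77 higher and 286 lower, all 40 among them. Leaving out 1 of the 10 compared libraries at a time gave 22 genes without mesotrione replicate 2, 23 without replicate 1, 26 without replicate 5, 26 without control replicate 2, 26 without control replicate 3 and 24 without control replicate 4, and single libraries left out ended the calls of CYP3A4, CYP1B1, CYP4F22, IGFL1, PGLYRP2 and IGFBP6. A pseudocount of 0.1 ended those of CYP3A4, AHSG, CYP4F22, VSIG1, IGFL1 and PGLYRP2 (CYP3A4 adjusted p = 0.188, AHSG adjusted p = 0.0569), no filter those of CYP3A4, CYP4F22, IGFL1 and PGLYRP2, median-ratio scaling those of CYP3A4, CYP1B1 and ASNS, and the 2 groups alone those of PGLYRP2 and the leukocyte list.

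Isoxaflutole at 1 mM raised CYP3A4, ANGPTL4 and PLIN2 and lowered AHSG, among other genes. CYP3A4 rose from 2.76 ± 0.216 to 174 ± 71.8 (log2 fold change 5.43, SE 0.35, adjusted p = 3.23e-16). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 2.45 ± 0.442 to 25.1 ± 5.93 (log2 fold change 2.91, SE 0.19, adjusted p = 3.23e-16; chromosome 19, 8363289 to 8374373). The lipid droplet coat genes PLIN4 and PLIN2 rose by 1.54 and 1.27 on the log2 scale, and PDK4, a kinase that restrains pyruvate oxidation, by 1.10. AHSG fell to 7.19 ± 2.94 (log2 fold change -3.15, SE 0.36, adjusted p = 9.11e-08).

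CYP1A1 rose with isoxaflutole from 0.547 ± 0.138 to 6.31 ± 4.88 (log2 fold change 2.03, SE 0.29, adjusted p = 1.21e-05), and TSKU rose by 1.14. OR2I1P and UBD, neighbours on opposite strands of chromosome 6 (29553219 to 29554166 and 29555515 to 29559925), rose by 1.57 and 1.41. They are uncertain as separate genes, because the strand setting of the assembly was not given in the sources used here. The alcohol dehydrogenase ADH4 and the complement chain C8G fell, with log2 fold changes of -2.37 and -2.09. VSIG1, COL3A1, PGLYRP2, EPYC and SFRP2 had log2 fold changes of -2.31, -2.07, -1.91, -1.89 and -1.85. CFHR2, which has near-identical paralogs and is uncertain, was listed at 0 in 2 isoxaflutole libraries and at 2.20, 2.27 and 3.35 FPKM in the other 3, against 6.25 to 19.1 in control.

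In all, 102 genes passed limma's test against control with isoxaflutole at 1 mM, 31 higher and 71 lower. Of 30 PPARalpha targets and fatty acid oxidation genes, 5 rose and none fell, namely ANGPTL4, PLIN2, PDK4, CIDEC by 1.05 and ACSL5 by 0.82. Adjusted over the list alone 6 were higher and 1 lower, and the list's adjusted p = 2.01e-12 became adjusted p = 0.408 with an estimated correlation. In 49 libraries 12 members were higher and 1 lower (adjusted p = 0.00598 with an estimated correlation). Of 18 targets of the receptors CAR and PXR, CYP3A4 rose, 3 being higher adjusted over the list alone (adjusted p = 1.06e-06, and adjusted p = 0.429 with an estimated correlation). Other members did not pass, among them UGT1A1 at 160 ± 52.3 against 58.4 ± 17.4, CYP3A5 at 41.4 ± 4.81 against 20.35 ± 5.46 and CYP2B6 at 4.92 ± 1.12 against 2.76 ± 1.60. With 49 libraries CYP3A5 passed (adjusted p = 0.00912) and UGT1A1 and CYP2B6 did not (adjusted p = 0.143 and 0.197). UGT1A genes share exons and CYP3A genes share sequence, so these levels are uncertain. Of 22 hepatocyte markers 3 fell and none rose, AHSG and TFR2 among them, 3 also adjusted over the list alone (adjusted p = 5.29e-07, and adjusted p = 0.487 with an estimated correlation). Beside them the stellate markers COL3A1 and DCN fell, 2 also adjusted over the list alone (adjusted p = 2.12e-05, and adjusted p = 0.487 with an estimated correlation). In the urea cycle list ARG1 fell by 1.35, and 3 were lower adjusted over the list alone (adjusted p = 4.86e-05, and adjusted p = 0.487 with an estimated correlation). CYP1A1 rose in the AHR list, 2 adjusted over the list alone (adjusted p = 0.000138, and adjusted p = 0.248 with an estimated correlation). ASNS rose by 0.68 in the stress response list, 4 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.756 with an estimated correlation). NRF2 targets and metallothioneins ranked higher and acute phase genes lower with no member past the threshold. Adjusted over the list alone 1 NRF2 target was higher and 2 acute phase genes were lower. Their adjusted p were 1.61e-05, 0.0396 and 0.0156, and the adjusted p with an estimated correlation were 0.487, 0.487 and 0.886. With 49 libraries 7 NRF2 targets were higher, no metallothionein passed, and the acute phase genes CRP and HP were lower (log2 fold changes -2.78 and -1.91, adjusted p = 0.00421 and 0.0259). Control varied widely in both, CRP lying at 2.83 ± 0.725 against 34.6 ± 38.1 and HP at 354 ± 116 against 1533 ± 1258, with HP at 3770 in control replicate 5 and at 790 to 1090 in the other 4. None of the 5 tyrosine degradation genes passed, HPD lying at 16.1 ± 3.12 against 24.6 ± 2.64 (log2 fold change -0.59, adjusted p = 0.965, with 49 libraries adjusted p = 0.00695), and the list's median of 0.16 and mean of -0.06 differed in sign. Without the library high in ribosomal RNA 878 genes passed, 439 higher and 439 lower, all 102 among them. Leaving out isoxaflutole replicate 1 gave 66 genes without OR2I1P and UBD, whose calls other single libraries left out, a pseudocount of 0.1 (adjusted p = 0.363 and 0.0842) and no filter (adjusted p = 0.0592 and 0.0543) also ended, and median-ratio scaling ended that of PDK4 (adjusted p = 0.0942). Scaling and the 2 groups alone ended the calls of the metallothionein and stress response lists, the pseudocount and 49 libraries that of metallothioneins, and no filter that of acute phase genes.

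Quizalofop-p-ethyl at 1 mM changed far more genes. PLIN2, a lipid droplet coat protein, rose from 35.03 ± 1.78 to 707 ± 187 (log2 fold change 4.26, SE 0.15, adjusted p = 6.63e-28; chromosome 9, 19108375 to 19149290). TRIB3, a pseudokinase induced by amino acid and ER stress, rose from 11.3 ± 0.774 to 234 ± 59.1 (log2 fold change 4.22, SE 0.15, adjusted p = 6.63e-28; chromosome 20, 362835 to 397559). AHSG fell to 0.612 ± 0.441 (log2 fold change -5.44, SE 0.36, adjusted p = 6.36e-17).

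CYP1A1 rose with quizalofop-p-ethyl from 0.547 ± 0.138 to 73.6 ± 33.9 (log2 fold change 5.46, SE 0.29, adjusted p = 1.46e-20; chromosome 15, 74719542 to 74725610). ANGPTL4 and the fatty acid carrier FABP4 rose by 4.85 and 4.25. The stress genes ATF3 and CHAC1 rose by 3.61 and 3.52, the uridine enzyme UPP1 by 3.85, the growth factor AREG by 3.67 and the neuropeptide precursor TAC1 by 3.61. The plasma protein genes SERPINA7, HRG, SERPINF2 and FGB, the last a fibrinogen chain, fell, with log2 fold changes of -5.41, -5.19, -5.08 and -4.96. The carbonic anhydrase CA9 had a log2 fold change of -4.97. HP, the gene of haptoglobin, fell from 1533 ± 1258 to 40.2 ± 53.6 (log2 fold change -5.74; chromosome 16, 72054592 to 72061055), and is uncertain because of its paralog HPR. HIST1H3B had a log2 fold change of -5.01, and HIST1H2AH was listed at 0 in 3 quizalofop-p-ethyl libraries and at 3.28 and 11.3 in the other 2, against 93.9 to 148 in control. Both histones belong to a family of near-identical copies and are uncertain.

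In all, 4819 genes passed limma's test against control with quizalofop-p-ethyl at 1 mM, 1700 higher and 3119 lower. Of 24 genes of the unfolded protein and integrated stress response 16 rose and PDIA4 fell, with the same counts adjusted over the list alone. Besides TRIB3, ATF3 and CHAC1, ASNS rose from 9.61 ± 0.791 to 99.7 ± 9.51. That list's adjusted p = 7.99e-24 became adjusted p = 0.0574 with an estimated correlation. All 21 cell cycle genes fell, 21 also adjusted over the list alone (adjusted p = 5.85e-19, and adjusted p = 0.145 with an estimated correlation). Among them were RRM2, MKI67 and TOP2A, with log2 fold changes of -3.93, -3.62 and -3.29. Of 22 hepatocyte markers 21 fell and none rose, 21 also adjusted over the list alone (adjusted p = 1.51e-23, and adjusted p = 0.124 with an estimated correlation). APOC3 and APOH had log2 fold changes of -4.56 and -4.49, and CEBPA did not pass (-0.45, adjusted p = 0.275, with 49 libraries adjusted p = 0.000458). ALB lay at 57.3 to 2719 FPKM in the 5 libraries against 8579 to 10320 in control (log2 fold change -4.21, adjusted p = 7.5e-09). Lists of markers of other cell types moved beside them. These cultures hold hepatocyte-like and biliary-like cells, so the stellate and leukocyte lists may not mark separate cell types. Of 10 biliary markers 6 fell, of 12 stellate markers 7 fell and 1 rose, and of 4 leukocyte markers 2 fell, with log2 fold changes of -3.00 for CD24, -2.21 for KRT19, -2.97 for FN1 and -1.88 for LYZ. Adjusted over the list alone 7 biliary markers were lower, 10 stellate markers lower and 1 higher, and 3 leukocyte markers lower. Their adjusted p were 0.00127, 6.32e-05 and 0.0249, with adjusted p = 0.266 with an estimated correlation for each. With 49 libraries the adjusted p with an estimated correlation was 0.0161 for the stress response, 0.00724 for the cell cycle, 0.0344 for hepatocyte markers and 0.0198 for biliary as for stellate markers. Without the library high in ribosomal RNA 8516 genes passed, 3471 higher and 5045 lower, all 4819 among them.

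Genes of metabolism divided with quizalofop-p-ethyl at 1 mM. Of 30 PPARalpha targets and fatty acid oxidation genes 10 rose and 10 fell (10 and 11 adjusted over the list alone). Those that rose included ANGPTL4, PLIN2, PDK4 by 3.16, ACSL1 by 1.47 and CPT1A, the entry step of mitochondrial fatty acid oxidation, by 1.00. Those that fell included VNN1, CYP4A11, the peroxisomal enzyme EHHADH and the lipid droplet gene CIDEC, with log2 fold changes of -3.26, -2.39, -1.94 and -0.88. The list's median of -0.23 and mean of 0.04 differed in sign, and it was not called (adjusted p = 0.124). Of 22 NRF2 targets 10 rose and 2 fell, also adjusted over the list alone (adjusted p = 1.26e-06, and adjusted p = 0.266 with an estimated correlation). SLC7A11 rose by 2.94, HMOX1 by 2.93, SRXN1 by 2.82 and GCLM by 2.11. Of 18 CAR and PXR targets 11 fell and 2 rose, 12 and 2 adjusted over the list alone (adjusted p = 2.28e-05, and adjusted p = 0.266 with an estimated correlation). GSTA2, GSTA1, CYP2C8 and CYP3A4 had log2 fold changes of -4.38, -4.32, -4.13 and -1.13, and the cytochrome P450 reductase POR rose by 2.34. GSTA1 and GSTA2 share sequence and are uncertain. Of 9 AHR targets 4 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.00436, and adjusted p = 0.266 with an estimated correlation). CYP1B1 rose by 3.43 and ALDH3A1 fell from 168 ± 20.8 to 45.1 ± 19.4. Of 5 genes in the tyrosine degradation list 3 fell, HPD and HGD among them, 3 also adjusted over the list alone (adjusted p = 0.00442, and adjusted p = 0.266 with an estimated correlation). HPD and HGD had log2 fold changes of -2.46 and -1.66. Of 20 acute phase genes 13 fell and 2 rose (15 and 2 adjusted over the list alone), of 13 urea cycle genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), and of 11 bile acid genes 6 fell (9 adjusted over the list alone). Their adjusted p were 1.4e-05, 0.000261 and 0.000417, with adjusted p = 0.266 with an estimated correlation for each. Of 13 interferon response genes 9 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00206, and adjusted p = 0.44 with an estimated correlation). Scaling, the 2 groups alone and 49 libraries ended the calls of the AHR and leukocyte lists (adjusted p = 0.057 and 0.0575 with 49 libraries). Mitochondrially encoded genes were not read here, since MT-CO1 was listed at 0 in 41 of 50 libraries and MT-CO3 in 5.

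**Figure D2:**
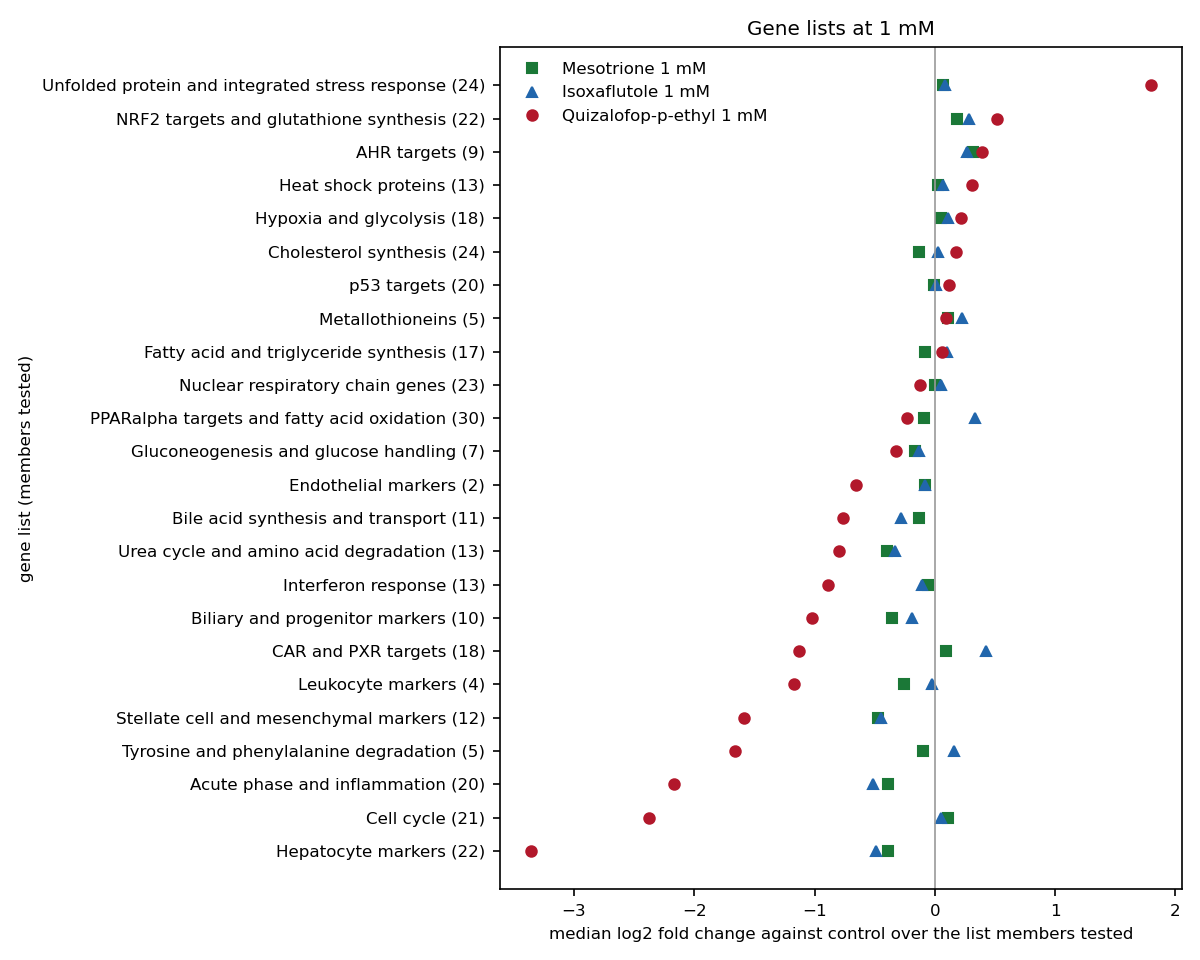
Median log2 fold change against control (horizontal axis) over the tested members of 24 gene lists (vertical axis, number of members in brackets) at 1 mM of mesotrione (squares), isoxaflutole (triangles) and quizalofop-p-ethyl (circles). With quizalofop-p-ethyl the stress response list has a median of 1.80 and the hepatocyte markers a median of -3.36, the latter against -0.39 with mesotrione and -0.49 with isoxaflutole.

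At 10 uM and 0.1 uM no gene passed limma's test against control for any of the 3 compounds with 50 libraries. CYP3A4 was 5.79 ± 3.43 with mesotrione and 5.67 ± 2.60 with isoxaflutole at 10 uM, and 7.53 ± 4.05 with isoxaflutole at 0.1 uM, against 2.76 ± 0.216 in control. The last of these gave a log2 difference of 1.04 with a 95% interval of 0.35 to 1.74 before adjustment and an adjusted p = 1 in limma. PLIN2 lay within 0.10 of control on the log2 scale in all 6 groups, with no 95% interval end beyond 0.39. Counts at an unadjusted p under 0.05 were 232 for mesotrione and 320 for isoxaflutole at 10 uM, where 984 would come by chance. At 0.1 uM they were 330, 371 and 287 for mesotrione, isoxaflutole and quizalofop-p-ethyl. Without replicate 5 of quizalofop-p-ethyl at 10 uM these 5 counts were 531, 887, 692, 1016 and 659. All 5 were higher than with that replicate, so part of the shortfall from 984 went with it. Counts far under 984 point to a test that calls too few genes, so they do not show that nothing changed. Quizalofop-p-ethyl at 10 uM gave 4115 such genes, and 956 without that replicate. Its median log2 fold change over all genes was -0.33 as deposited, -0.11 with median-ratio scaling and 0.03 without replicate 5. Over the 8748 genes with a mean of 5 FPKM or more the 95% interval reached 0.53 to either side of a difference, by its median, and 0.24 to 0.26 with 49 libraries.

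With 49 libraries 2 genes passed at 10 uM of quizalofop-p-ethyl, named here although chosen after their values were seen. COL8A1, a collagen chain, was 14.8 ± 1.42 in 4 libraries against 7.46 ± 0.83 in control (log2 fold change 0.90, SE 0.12, adjusted p = 0.000122; chromosome 3, 99638469 to 99799226). SUSD2, a membrane protein, was 59.9 ± 7.05 against 34.8 ± 3.13 (log2 fold change 0.77, SE 0.14, adjusted p = 0.0161; chromosome 22, 24181259 to 24189110). Leaving out replicate 2 in place of replicate 5 gave 4 genes. KDR and ESAM were the only members of the endothelial list tested, since PECAM1, VWF, CDH5 and the rest were too low. They may not mark endothelial cells here. KDR and ESAM ranked higher with mesotrione at 10 uM (adjusted p = 0.000777, and adjusted p = 0.00639 with an estimated correlation). They did so too with quizalofop-p-ethyl at 10 uM (adjusted p = 0.000223, and adjusted p = 0.00284 with an estimated correlation). Neither gene passed by itself, KDR lying at 2.82 ± 1.06 and 2.81 ± 1.65 against 1.65 ± 0.221, and 1 was higher adjusted over the list alone with mesotrione and none with quizalofop-p-ethyl. The bile acid list ranked higher with isoxaflutole at 0.1 uM, with no member past the threshold, also adjusted over the list alone (median log2 fold change 0.12, adjusted p = 0.0193, and adjusted p = 0.974 with an estimated correlation), a call that a pseudocount of 0.1 ended.

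**Figure D3:**
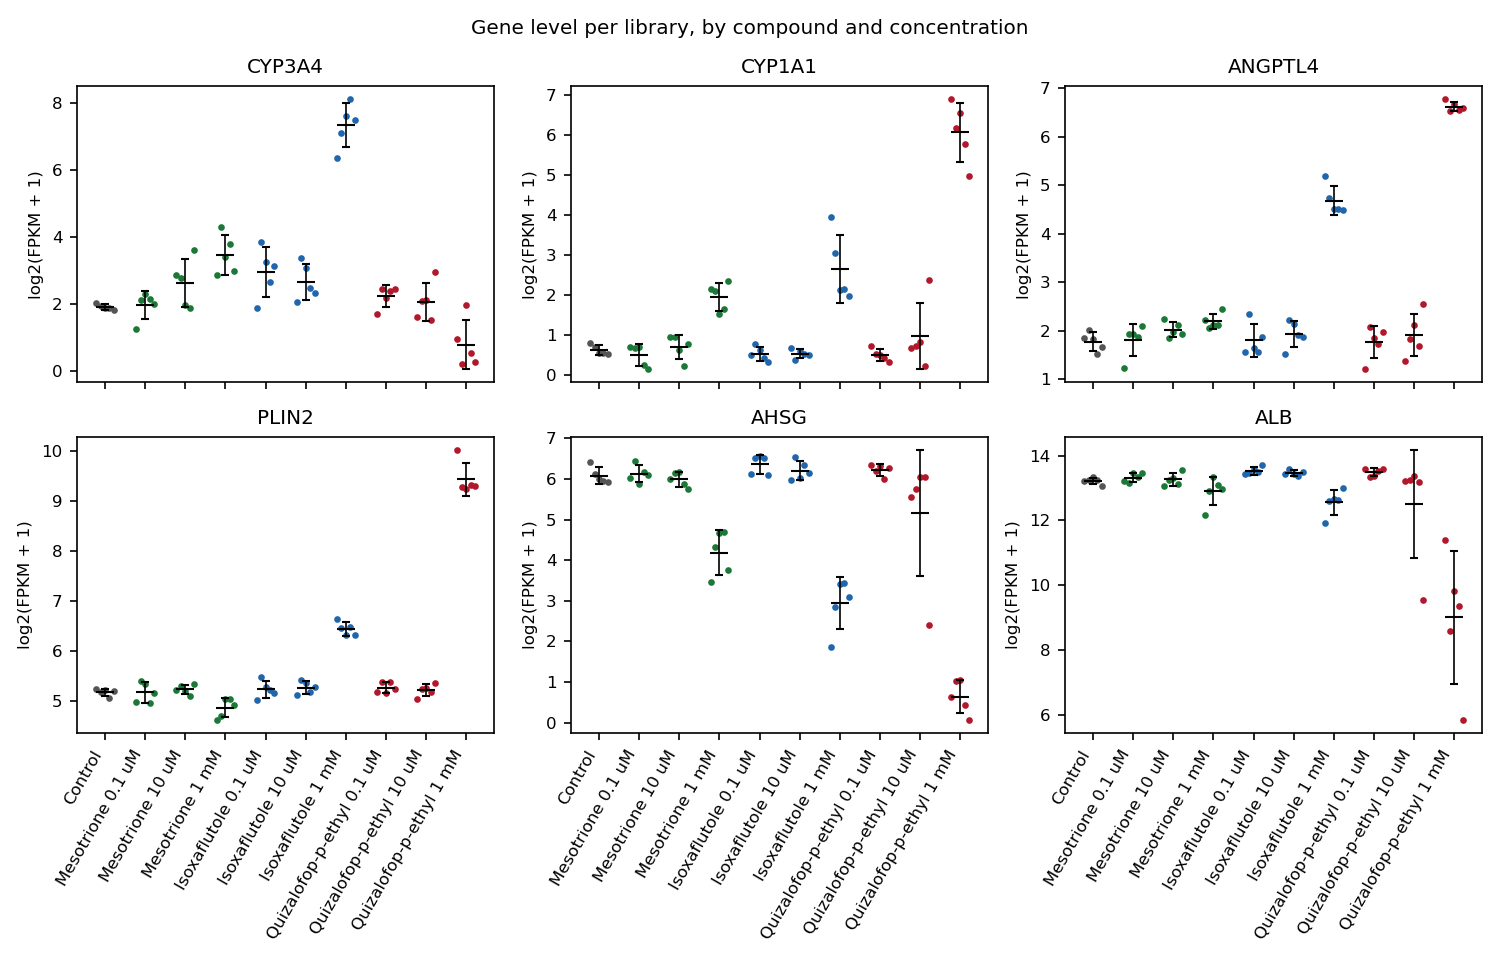
Level of CYP3A4, CYP1A1, ANGPTL4, PLIN2, AHSG and ALB, as log2(FPKM + 1) on the vertical axis, in each library (points) with the mean and SD (black) for control and the 3 concentrations of each compound. At 1 mM CYP3A4 has a mean of 174 FPKM with isoxaflutole and PLIN2 a mean of 707 FPKM with quizalofop-p-ethyl, against 2.76 and 35.03 FPKM in control, and the low AHSG and ALB point at 10 uM is replicate 5.

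Isoxaflutole and mesotrione share a plant target but differ in structure, an isoxazole against a triketone, and were compared directly at matched concentrations. At 1 mM CYP3A4 was higher with isoxaflutole by 3.87 on the log2 scale (95% interval 3.18 to 4.57, adjusted p = 6.88e-11). ANGPTL4 was higher by 2.49 (2.11 to 2.87, adjusted p = 2.6e-13) and PLIN2 by 1.59 (1.29 to 1.88, adjusted p = 1.35e-10). PLIN4 was higher by 1.90 and the lipid droplet gene CIDEC by 1.15, and FABP4 was 4.83 ± 1.55 with isoxaflutole but listed at 0 in 4 of 5 mesotrione libraries and at 0.0701 in replicate 3. These 6, with KCNK13, FP565324.1 and AP003119.3, were the 9 genes past limma's threshold, all higher with isoxaflutole. FABP4, KCNK13, FP565324.1 and AP003119.3 were chosen after their values were seen. Of 30 PPARalpha targets 3 were higher, 9 adjusted over the list alone (adjusted p = 6.6e-31, and adjusted p = 0.0282 with an estimated correlation). Of 18 CAR and PXR targets 1 was higher, 2 adjusted over the list alone (adjusted p = 2.94e-09, and adjusted p = 0.259 with an estimated correlation). Fatty acid synthesis and leukocyte lists ranked higher (adjusted p = 0.00289 each, and adjusted p = 0.948 and 0.316 with an estimated correlation), as did cholesterol synthesis and metallothioneins (adjusted p = 0.0253 and 0.0323, and adjusted p = 0.948 and 0.578 with an estimated correlation). No member of these 4 lists passed, and 1 leukocyte marker was higher adjusted over the list alone. With 49 libraries 12 PPARalpha targets, 3 CAR and PXR targets, 1 fatty acid synthesis gene and 1 leukocyte marker were higher. AHSG did not pass (difference -1.25, 95% interval -1.98 to -0.52 before adjustment, adjusted p = 0.632, with 49 libraries adjusted p = 0.000518). Nor did CYP1A1 (0.70, 0.11 to 1.28, adjusted p = 1) or ALB (-0.34, -1.38 to 0.71, adjusted p = 1), with 49 libraries adjusted p = 0.377 and 0.925. With 49 libraries 99 genes differed, 90 higher and 9 lower, and with median-ratio scaling the higher share was 87.2% in place of 100%.

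At 10 uM and 0.1 uM no gene differed between isoxaflutole and mesotrione in limma, with 305 and 377 genes at an unadjusted p under 0.05 where 984 would come by chance. Without replicate 5 of quizalofop-p-ethyl at 10 uM in the fit these were 894 and 907. Here too, the counts of 305 and 377, far under 984, do not show that nothing differed. Those without replicate 5 lay nearer to 984, so much of the shortfall went with that library in the fit. The 95% interval of the CYP3A4 difference was -0.66 to 0.73 at 10 uM and 0.29 to 1.68 at 0.1 uM before adjustment, and that of PLIN2 was -0.26 to 0.33 and -0.23 to 0.36. The CAR and PXR list ranked higher with isoxaflutole at 0.1 uM with no member past the threshold (median 0.35, adjusted p = 0.000953, and adjusted p = 0.97 with an estimated correlation).

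Quizalofop-p-ethyl at 1 mM was compared directly with each of the other compounds. Against mesotrione, PLIN2 was higher by 4.58 (SE 0.15, adjusted p = 5.34e-29), ANGPTL4 by 4.43, and FABP4 lay at 29.5 ± 16.6 FPKM. GSTA2 and HIST1H3B were lower, with log2 differences of -5.14 and -5.11. Against isoxaflutole, TRIB3 was higher by 3.92 (SE 0.15, adjusted p = 3.64e-26), UPP1 by 3.74 and the nerve growth factor receptor gene NGFR by 3.67. CYP3A4 was lower, at 0.922 ± 1.14 against 174 ± 71.8 (log2 difference -6.56, SE 0.35, adjusted p = 1.75e-20), as was the glutathione peroxidase GPX2 (-4.99). HIST1H2AH, listed at 0 in 3 quizalofop-p-ethyl libraries, lay between 115 and 150 FPKM with mesotrione and between 78.7 and 146 with isoxaflutole. In total 4181 genes differed from mesotrione, 1621 higher and 2560 lower, and 4140 from isoxaflutole, 1495 higher and 2645 lower. Of 24 stress response genes 16 were higher than with mesotrione, 16 adjusted over the list alone (adjusted p = 2.31e-24, and adjusted p = 0.0518 with an estimated correlation). The same number was higher than with isoxaflutole, 17 adjusted over the list alone (adjusted p = 1.95e-25, and adjusted p = 0.0422 with an estimated correlation). All 21 cell cycle genes were lower in both comparisons, also adjusted over the list alone. Their adjusted p were 1.06e-23 and 2.65e-23, and the adjusted p with an estimated correlation were 0.0989 and 0.0995. Of 22 hepatocyte markers 20 were lower than with mesotrione and 21 lower than with isoxaflutole, also adjusted over the list alone. Their adjusted p were 1.22e-21 and 1.3e-20, and the adjusted p with an estimated correlation were 0.113 and 0.0995. Of 18 CAR and PXR targets 14 were lower and 1 higher than with isoxaflutole, also adjusted over the list alone (adjusted p = 3.18e-11, and adjusted p = 0.0995 with an estimated correlation). With 49 libraries 8047 and 7921 genes differed.

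At 10 uM CDH16, a cadherin chosen after its values were seen, was lower with quizalofop-p-ethyl than with mesotrione, at 1.32 ± 0.629 against 3.11 ± 0.457 (log2 difference -0.86, SE 0.16, adjusted p = 0.0303). It was the 1 gene past limma's threshold, with 3608 at an unadjusted p under 0.05, and 1149 without quizalofop-p-ethyl replicate 5. That call was lost without mesotrione replicate 1, 2, 3 or 5 and without quizalofop-p-ethyl replicate 1 or 4, and with a pseudocount of 0.1, no filter, scaling or the 2 groups alone, each leaving 0 genes. Without quizalofop-p-ethyl replicate 2 there were 2 genes, and without replicate 5 the 5 genes CDH16, SUSD2, COL8A1, FHL1 and EPYC. Against isoxaflutole at 10 uM no gene passed in limma, with 4399 at an unadjusted p under 0.05. Without replicate 5 that count was 897, and the 2 genes SUSD2 and COL8A1 passed. KDR and ESAM ranked higher than with isoxaflutole (adjusted p = 0.0151, and adjusted p = 0.0421 with an estimated correlation), and the nuclear respiratory chain genes ranked lower (adjusted p = 0.0378, and adjusted p = 0.934 with an estimated correlation). Both list calls include replicate 5. The median log2 fold change of this comparison over all genes was -0.34 with that replicate and 0.02 without it. At 0.1 uM quizalofop-p-ethyl differed from mesotrione and isoxaflutole in 0 genes in limma, with 380 and 262 at an unadjusted p under 0.05, and 802 and 526 with 49 libraries. The CYP3A4 difference from isoxaflutole was -0.72 (95% interval -1.42 to -0.02 before adjustment, adjusted p = 1), and the CAR and PXR list ranked lower (adjusted p = 0.0114, and adjusted p = 0.964 with an estimated correlation).

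The genes called for different compounds at 1 mM overlapped. Mesotrione and isoxaflutole shared 3 genes higher and 27 lower, among the latter COL3A1 and AHSG. Independent lists of those sizes would share 0.00945 and 0.123. Mesotrione and quizalofop-p-ethyl shared 4 higher and 34 lower, against 0.518 and 5.39, and 2 genes moved in opposite directions. Isoxaflutole and quizalofop-p-ethyl shared 17 higher, with ANGPTL4 and PLIN2 among them, and 70 lower, against 2.68 and 11.3. Another 6 genes, CYP3A4 among them, moved in opposite directions. With 49 libraries the 3 pairs shared 54, 50 and 225 genes higher and 217, 251 and 369 lower, and 1, 21 and 109 genes moved in opposite directions. Independent lists would then share 1.72, 13.6 and 77.4 higher and 6.38, 73.3 and 113 lower. With the controls split between the comparisons in 20 ways, the median overlaps higher and lower with 50 libraries were 0 and 7, 0 and 10, and 7.5 and 31. With 49 libraries they were 11.5 and 80.5, 17.5 and 116, and 104 and 210. Each comparison then has fewer controls, so these smaller overlaps mix lost power with the removal of shared controls. In 50 simulations of unchanged groups with shared controls the overlaps at 1 mM were 0 in every draw. No gene was changed in these simulations, so few calls were due in them. The 0 therefore does not show how much shared controls add to the overlap of genes that did change. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.0548, 0.0819 and 0.0917 for the 3 pairs, against 0.0303, 0.0294 and 0.0317 in 50 simulations of unchanged groups with the same controls. The differences were 0.0245, 0.0525 and 0.0601. At 10 uM the covariance was 0.0245, 0.0296 and 0.0298, against the same simulated values.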

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

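Of the tests in this part, those of depth, of ribosomal RNA, of cell shares and of scaling were chosen after the result was seen. In each group of 5, a library was listed when its gap to the nearest other divided by the group's range exceeded Dixon's 95% critical value, which chance gives in about 1 group in 20. Of 160 groups 24 had such a library, 15%.

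The first pattern is replicate 5 of quizalofop-p-ethyl at 10 uM, with 6583 genes at 1 FPKM or more, ALB at 746.8 FPKM, RN7SK at 6.175% and ribosomal RNA loci at 52.73% of the summed FPKM. Fewer fragments alone would leave FPKM at the level of the group, but over 976 genes above 50 FPKM the median ratio to the other 4 libraries was 0.126, against 0.919 to 1.07 for other libraries, which argues against it. Ribosomal RNA left in the library is a candidate explanation for these low values, with 52.7% at its loci against 1.10% to 3.79% in the other 49. FPKM scales by length, so this is not a share of fragments. Whether it is large enough to give a median ratio of 0.126 was not tested. Ribosomal RNA would lower all genes alike. It does not account for CYP1A1 at 4.232 FPKM (0.1796 to 0.7889 in the other 4), ANGPTL4 at 4.842 (1.601 to 3.313), CYP3A4 at 6.694 (1.832 to 3.336) or PLIN2 at 40.12 (31.67 to 37.39), which stay open. No biological explanation was tested for a single library.

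The second pattern is the fall of hepatocyte markers with quizalofop-p-ethyl at 1 mM, a median log2 fold change of -3.36 (95% interval -4.28 to -2.54) over 22 genes. The intervals of these list medians come from resampling the genes of a list, not the libraries. Genes of a list are not independent replicates, so the intervals may be too narrow. A lower share of hepatocyte-like cells alone would raise the markers of other cells, but the biliary markers had a median of -1.02 (95% interval -2.07 to -0.111) and the stellate markers one of -1.59 (-2.55 to -0.64). The biliary markers fell less than the hepatocyte markers, so a lower share together with a fall in other cells is not excluded. These cultures hold hepatocyte-like and biliary-like cells, so the stellate list may not mark a separate cell type. Median-ratio scaling left 22 of 22 lower (median -3.39), and leaving out 1 quizalofop-p-ethyl library left at least 20, so neither scaling nor 1 library accounts for it. A lower expression of these genes within the cells may account for it too, a hypothesis found on the same data that was not tested by itself. Loss or damage of cells of all types was not tested.

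The third pattern is that 14 of the 24 listed values lay in libraries with sample numbers 9 to 18, 7 of them in control replicate 5. A batch shared by these 10 libraries would make their deviations from the group means correlate. Their mean correlation was 0.0735, against 0.00292, 0.0262, 0.0158 and 0.0186 in the other runs of numbers, with a permutation p of 0.0001, the smallest that 10000 shufflings can give. It stayed under the bound of 0.1 set before, but the highest shuffling reached 0.0579, so that bound was too high and the deviations were shared beyond these shufflings. Whether a technical batch or a difference between cultures is shared cannot be told apart, since the labels give neither, and no biological explanation was tested.

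Far from the rest of their group were also, in control replicate 5, OR2I1P at 13.71, UBD at 29.5, CFHR2 at 19.07, C8G at 25.54, HP at 3774, HRG at 115.2 and CA9 at 20.96 FPKM. In replicate 1 of quizalofop-p-ethyl at 1 mM they were PLIN2 at 1040, AREG at 75.3 and HP at 135 FPKM and the summed FPKM of 569300. In isoxaflutole at 1 mM they were PLIN4 at 34.86 FPKM, RN7SK at 14.32% and ribosomal RNA loci at 2.913% in replicate 1, and PDK4 at 15.71 FPKM in replicate 5. In mesotrione at 1 mM they were IGFBP6 at 4.293 and FABP4 at 0.07014 FPKM in replicate 3 and a summed FPKM of 751600 in replicate 2. The last were RN7SK at 3.419% in replicate 2 of quizalofop-p-ethyl at 0.1 uM and 17540 genes at 1 FPKM or more in control replicate 2.

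Differences between compounds passed limma's direct test in 9 genes for isoxaflutole against mesotrione at 1 mM, and in 4181 and 4140 genes for quizalofop-p-ethyl against mesotrione and against isoxaflutole at 1 mM. At 10 uM 1 gene differed between quizalofop-p-ethyl and mesotrione.

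Each comparison was set against 100 of the 126 splits of its 10 libraries, the real one included. At 1 mM 1 split, the real one, gave as many genes for mesotrione (40, highest other 1), isoxaflutole (102, highest other 1) and quizalofop-p-ethyl (4819, highest other 1415) against control. The same held for isoxaflutole against mesotrione (9, highest other 1) and for quizalofop-p-ethyl against mesotrione (4181, highest other 1227) and against isoxaflutole (4140, highest other 1151). For these 6 the share of 1 in 100 is the smallest these splits can give, so a chance division of these libraries is unlikely. The labels do not say that libraries of a group came from separate cultures, so a chance difference between cultures is not excluded. For the 1 gene between quizalofop-p-ethyl and mesotrione at 10 uM, 23 splits gave as many and 1 gave 18, so chance is not excluded. A split with 18 genes points to a structure of the samples, which was not tested, and replicate 5, apart from its group, is among the 10 libraries split. The comparisons with 0 genes in limma are matched by all 100 splits. Any split matches a count of 0, so this test cannot speak for or against chance there. Their highest other counts against control were 2 and 1 for mesotrione, 1 and 3 for isoxaflutole and 6 and 0 for quizalofop-p-ethyl at 10 uM and 0.1 uM. For the direct comparisons with 0 genes they were 2 and 2 for isoxaflutole against mesotrione at 10 uM and 0.1 uM, 1 for quizalofop-p-ethyl against mesotrione at 0.1 uM, and 5 and 1 against isoxaflutole. The unadjusted counts of these comparisons stand in the report.

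Counts of gene lists separate less well. At 1 mM, 2 splits gave as many lists as isoxaflutole (10, highest other 11), a share under 0.05 although 1 other split gave more, but 7 gave as many as mesotrione (10, highest other 13) and 12 as many as quizalofop-p-ethyl (14, highest other 17), so chance is not excluded for these 2 counts of lists. A split into 3 and 2 of each group still carries part of a treatment effect, and for the genes of both compounds no other split drawn gave as many. At 10 uM, 64 splits gave as many as mesotrione (1, highest other 11), 82 as many as quizalofop-p-ethyl (2, highest other 9) and all 100 as many as isoxaflutole (0, highest other 4). At 0.1 uM, 52 gave as many as isoxaflutole (1, highest other 6), and all 100 as many as mesotrione (0, highest other 3) and quizalofop-p-ethyl (0, highest other 5). For the counts of 0 lists this was fixed beforehand, since any split matches 0.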

How the results depend on the processing

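The fit of 49 libraries was chosen after seeing the data, and the other settings before. Counts below moved by over 1.5 times or changed between 0 and a count, and the cause was not tested unless given. The counts with 50 libraries were, at 1 mM, 40 for mesotrione, 102 for isoxaflutole and 4819 for quizalofop-p-ethyl against control, 9 for isoxaflutole against mesotrione, and 4181 and 4140 for quizalofop-p-ethyl against mesotrione and isoxaflutole, 1 gene for quizalofop-p-ethyl against mesotrione at 10 uM, and 0 in limma elsewhere, with unadjusted counts in the report. Without replicate 5 of quizalofop-p-ethyl at 10 uM (49 libraries) these 6 counts at 1 mM became 363, 878, 8516, 99, 8047 and 7921, and quizalofop-p-ethyl at 10 uM gave 2 genes against control, 5 against mesotrione and 2 against isoxaflutole. Median-ratio scaling gave 162, 442, 7357, 47, 6758 and 6680 at 1 mM, and at 10 uM 2 genes for quizalofop-p-ethyl against control, 0 against mesotrione and 1 against isoxaflutole. Fits of the 2 groups alone gave 195, 679, 7510, 49, 6826 and 6759, with 1 gene for mesotrione at 0.1 uM and, at 10 uM, 6 for quizalofop-p-ethyl against control, 1 for isoxaflutole against mesotrione, and 0 and 2 for quizalofop-p-ethyl against mesotrione and isoxaflutole. At 0.1 uM that fit gave 1 for quizalofop-p-ethyl against isoxaflutole. A pseudocount of 0.1 gave 22 for mesotrione and 61 for isoxaflutole at 1 mM, and 0 for quizalofop-p-ethyl against mesotrione at 10 uM. With no filter on low values quizalofop-p-ethyl gave 0 genes against mesotrione and 1 against isoxaflutole at 10 uM, and 1 against mesotrione at 0.1 uM. Tested by transcript, 54989 in all, the genes with a transcript past the threshold were 11 for mesotrione, 35 for isoxaflutole, 4 for isoxaflutole against mesotrione and 2758 for quizalofop-p-ethyl against isoxaflutole at 1 mM. By transcript there were 2 for mesotrione, 2 for isoxaflutole and 3 for quizalofop-p-ethyl at 10 uM, 2 each for isoxaflutole and quizalofop-p-ethyl at 0.1 uM, and 0 for quizalofop-p-ethyl against mesotrione at 10 uM. The runs of sample numbers as a block gave 61 genes for mesotrione at 1 mM and 3 lists for isoxaflutole at 0.1 uM in place of 1, and moved no other count by over 1.5 times. The block lost none of the calls of named genes, and none of the calls of lists against control. Libraries of a run correlated from -0.127 to 0.191 in their deviations, and in no comparison were all 5 pairs over 0.1, the rule set for pairing, so the samples were not taken as paired. That rule looks only at pairs within a comparison, and the run numbered 9 to 18 shared deviations, with a mean correlation of 0.0735. The lists called for isoxaflutole at 0.1 uM were 6 with 49 libraries, 6 with scaling, 6 with the 2 groups alone, 0 with the pseudocount of 0.1 and 0 with an estimated correlation. For quizalofop-p-ethyl at 10 uM 15 lists in place of 2 were called with no filter, and for mesotrione at 10 uM 3 in place of 1 with the 2 groups alone. An estimated correlation left 1 of 10 lists for mesotrione, 0 of 10 for isoxaflutole and 0 of 14 for quizalofop-p-ethyl at 1 mM. The mitochondrially encoded list turned from higher to lower at 10 uM of quizalofop-p-ethyl with 49 libraries (adjusted p = 0.492, against 0.00245 with 50 and 0.000209 to 0.439 in its other alternatives). Of 38 list calls against control 34 were lost with an estimated correlation, 5 with scaling, 5 with the 2 groups alone, 4 with 49 libraries, the turned list among them, 2 with no filter, 2 with the pseudocount and none with the block. Lists called in the direct comparisons were not tested under scaling, the 2 groups alone, no filter, the pseudocount or the block. Of 68 calls of named genes 9 were lost with the pseudocount, 7 with no filter, 4 with scaling, 1 with the 2 groups alone and none with 49 libraries or the block, those printed being named in the report beside their results, and with 1 library left out 627 such calls stayed and 53 were lost. Leaving out 1 of the 10 libraries compared gave 22 to 34 genes for mesotrione, 66 to 87 for isoxaflutole and 4004 to 4564 for quizalofop-p-ethyl against control at 1 mM, 7 to 10 for isoxaflutole against mesotrione, 3401 to 3900 for quizalofop-p-ethyl against mesotrione and 3368 to 3893 against isoxaflutole. At 10 uM it gave 0 to 4 for quizalofop-p-ethyl against control, 0 to 5 against mesotrione and 0 to 2 against isoxaflutole, and 0 to 0 in the other comparisons. Replicate 5 of quizalofop-p-ethyl at 10 uM limits the calls through the spread it adds. It was shallow, with an estimated 3780000 fragments, and high in ribosomal RNA, with 52.7% of its summed FPKM at those loci. Which of these adds the spread was not separated.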

Other observations

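Tests of the score below were chosen before the result was seen, and the genes COL8A1, SUSD2 and EPYC after it. Further gene lists were tested with quizalofop-p-ethyl at 1 mM, and of those below only the interferon list was called. Of 20 p53 targets 4 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.0695). GDF15, a stress-induced secreted factor, rose from 110 ± 35.4 to 1238 ± 661 FPKM (log2 fold change 3.38, adjusted p = 3.39e-14), PHLDA3 by 1.48, BBC3 by 0.95 and CDKN1A, a brake on the cell cycle, by 0.77, and TP53INP1 had a log2 fold change of -1.05. Of 18 hypoxia and glycolysis genes 4 rose and 3 fell, 6 and 4 adjusted over the list alone (adjusted p = 0.201). VEGFA, a growth factor for vessels, rose by 2.00 and the glucose transporter SLC2A1 by 1.90, and CA9 and PFKFB3 had log2 fold changes of -4.97 and -1.71. Of 7 genes of glucose handling 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.635), IGFBP1 by 2.55 and PCK2 by 1.45, with -1.71 for G6PC and -1.39 for SLC37A4.

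Of 17 fatty acid and triglyceride synthesis genes 1 rose and 3 fell, 1 and 2 adjusted over the list alone (adjusted p = 0.847). SCD, a desaturase, rose from 232 ± 11.9 to 564 ± 287 FPKM, and SREBF1, DGAT2 and PNPLA3 had log2 fold changes of -1.03, -0.79 and -0.73. Of 24 genes in the cholesterol synthesis list 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.154), with MVD higher by 0.78 and DHCR7 by 0.64. Of 13 heat shock genes 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.13), HSPH1 by 0.72 and HSPD1 by 0.68, with -1.08 for HSPB1. Of 5 metallothioneins MT1X rose by 1.11 and MT1E fell by 1.27, also adjusted over the list alone (adjusted p = 0.654), and as close paralogs they are uncertain. The endothelial markers KDR and ESAM had log2 fold changes of -0.95 and -0.35 (list adjusted p = 0.109), both past the threshold and also adjusted over the list alone. None of 23 nuclear respiratory chain genes passed in limma (list adjusted p = 0.826), but 1 was higher and 6 were lower with 49 libraries. In the interferon list OAS3, OAS2 and IFI6 had log2 fold changes of -1.82, -1.65 and -1.49, and IRF7 rose.

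COL8A1, SUSD2 and EPYC lay higher than control in 4 libraries of quizalofop-p-ethyl at 10 uM, at 14.8 ± 1.42, 59.9 ± 7.05 and 11.8 ± 1.04 against 7.46 ± 0.83, 34.8 ± 3.13 and 6.79 ± 0.688 FPKM. With 49 libraries COL8A1 and SUSD2 passed against control at this concentration, while EPYC did not and passed only against mesotrione at 10 uM (adjusted p = 0.000213). At 1 mM of the same compound COL8A1 and SUSD2 fell to 1.21 ± 0.273 and 12.8 ± 2.08 (log2 fold changes -1.94 and -1.38, adjusted p = 1.1e-07 and 7.9e-05), and EPYC was listed at 0 in 1 library and at 0.0449 to 0.744 in the other 4. With mesotrione at 1 mM COL8A1 and SUSD2 were 4.52 ± 1.11 and 19.8 ± 3.14 (adjusted p = 0.873 and 0.533, with 49 libraries 0.000759 and 0.000119). With isoxaflutole at 1 mM they were 3.85 ± 0.422 and 16.3 ± 3.16 (adjusted p = 0.267 and 0.0531, with 49 libraries 7.01e-06 and 1.52e-07).

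A hypothesis was that quizalofop-p-ethyl at the lower concentrations gives a weaker form of its change at 1 mM. The score of a library was the mean log2 level of 595 genes higher minus that of 1183 genes lower, at least 2-fold, with quizalofop-p-ethyl than with mesotrione at 1 mM, a choice that uses no control library. Between quizalofop-p-ethyl at 1 mM and control it differed by 3.39, on genes chosen for their difference in those same 1 mM libraries. At 10 uM the 4 deeper quizalofop-p-ethyl libraries differed from the 10 of the other compounds by 0.00603 (95% interval -0.053 to 0.064, exact permutation p = 0.825 over 1001 permutations). At 0.1 uM 5 libraries differed from 10 by -0.00429 (95% interval -0.06 to 0.054, exact permutation p = 0.874 over 3003 permutations), and both adjusted p were 0.874. Replicate 5 of quizalofop-p-ethyl at 10 uM, left out of this test, had a score of 0.0539, against a mean of -1.11 in the other 4. Its low values across genes (median ratio to the other 4 of 0.126 over genes above 50 FPKM) draw such a score towards 0. Whether the low values account for all of this score was not tested. CYP1A1, ANGPTL4 and PLIN2, which rose with this compound at 1 mM, lay above the other 4 libraries in replicate 5. So did CYP3A4, which fell at 1 mM. Whether the score of replicate 5 holds a shift towards the 1 mM change stays open. In the libraries tested the hypothesis gained no support. The intervals leave out a difference beyond 0.064 from the other compounds at the same concentration, whereas the 3.39 at 1 mM is against control. A shift shared by all compounds would not show in this test. Control had a score of -1.08 ± 0.028, against -1.11 ± 0.027 in the 4 libraries at 10 uM and -1.14 ± 0.058 at 0.1 uM of quizalofop-p-ethyl.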
